A study of Mus musculus with 12 samples.

How the data were processed

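Total RNA of mouse bone marrow was analysed on Affymetrix whole-transcript arrays, with 4 arrays for each of 3 diets. Per the labels, RNA came from an RNeasy mini kit or its version for lipid tissue, and amplified, fragmented and labelled cDNA was hybridised. The deposited values are log2 signals per probe set, with array medians between 8.04 and 8.13. The submitters' processing notes name PLIER, and its version and settings, the background correction, the scaling between arrays and the genome build are not given in the sources used here, so no genome positions are printed. The log2 scale was read from the values, which run from 4.71 to 14.47. All 12 arrays were used, and the scale was taken as it stands, with no further normalization.

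Of 35556 probe sets, 21789 carried a single gene symbol, 1621 several and 12146 none in the probe table used here. Only the first kind entered the gene tests. By Entrez identifier 21698 of them matched a table of mouse RefSeq genes, and 0 symbols had to be updated. The probe set with the highest mean over the 12 arrays stood for its gene, giving 19938 genes. The lowest 30% of probe sets by mean signal, under log2 7.36, were left out, which left 15307 genes. The 8213 probe sets without a single symbol that passed the same filter were tested separately, and 0 passed in any comparison by limma, with 331 at an unadjusted p under 0.05 in PFD against SFD, 705 in PFD against LFD, 237 in SFD against LFD and 511 for both high fat diets against LFD.

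Groups were taken from the diet in the labels. No paired analysis was possible because the labels number the samples from 1 to 12 with no number shared between diets. Differences between diets were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 12 arrays in 3 groups, 9 residual and 8.04 prior degrees of freedom), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The comparisons were PFD minus SFD, PFD minus LFD, SFD minus LFD and the mean of PFD and SFD minus LFD. An SE is the moderated standard error of that fit, and an SD is taken over the arrays of a diet. An array counts as beyond another diet when its value lies outside all values of that diet in the direction of the difference.

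Gene lists were tested with limma's camera at a preset correlation between members of 0.01, adjusted over 51 lists of marrow cell types, neutrophil functions and metabolic and signalling pathways with at least 5 tested members each. The lists hold 1186 entries, of which 1001 (901 distinct genes) could be tested, and the others were not analysed here. The correlation was also estimated for each list, limma's fry tested whether the members of a list moved one way on balance, and the mean of each list per array was compared by an exact two-sided permutation test, whose smallest p with 4 arrays against 4 is 0.0286. Neither fry nor the exact test compares a list with other genes. Adjusted over 51 lists, the exact test can pass a list only if most lists lie at its smallest p. Its adjusted count could therefore hardly differ from 0.

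The named genes were chosen by a rule: in each comparison and direction the 12 largest differences among those that passed, and where fewer passed, further genes by smallest p up to 8, given as not passing. Gstm1, the 13th higher gene in PFD against SFD, falls outside this rule and was named after its values were seen. Predicted genes were not named. Up to 4 members of smallest p were named for each list described, and 20 further genes were named whatever their value, of which 3 were not analysed here and 1 was dim. The groups, comparisons, tests, gene lists, this rule and the alternative settings were fixed before the data were examined.

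The overlap of both PFD comparisons and the covariance of both differences from LFD were set beside simulated unchanged groups and beside splits of the shared arrays, and the overlap, in a simulation chosen after the data were seen, also beside groups with separate genes changed in SFD and in LFD. The same code was tested on data simulated 10 times with the means and spreads of the 15307 genes, with changes in PFD against SFD. Of 100 genes changed by 0.5 on the log2 scale 92 to 98 were recovered, and of 100 changed by 1, all 100 in every draw. In all 200 to 210 genes were called by limma, 5 to 14 of them falsely (2.44% to 6.70%, mean 4.74%), and at most 2 passed for SFD against LFD, which had no change. A list shifted by 0.2 was found in every draw (adjusted p at most 5.59e-05), and at most 1 other list passed. The simulated noise was independent between genes, so these draws do not show how the list test fares with correlated members. They also held no structure of the samples and many more changed genes than were called in the real data. Where fewer genes are called the adjusted threshold is stricter, so the recovery of a change of 0.5 is likely lower there. The share of false calls may differ too.

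The settings tried as alternatives were leaving out each array, quantile normalization, subtraction of array medians, no filter or a filter at 50%, the mean of all probe sets of a gene, fitting only the diets compared, an intensity trend with robust estimation, array weights, the code in the sample description as a random block (statmod 1.5.0), an adjusted p under 0.10 and, for lists, the estimated correlation and fry. Further settings, chosen after the data were seen, were the interquartile range of an array as a covariate, leaving out LFD 3 and PFD 6, the exact test of list means, and odd or even sample number as a covariate. Python 3.11.15 and matplotlib 3.10.9 drew the figures.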

Results

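Gene expression was profiled in bone marrow of uninfected male C57BL/6 mice kept on a low fat diet (LFD, arrays 1 to 4), a polyunsaturated high fat diet (PFD, arrays 5 to 8) or a saturated high fat diet (SFD, arrays 9 to 12). Each diet had 4 arrays, named by diet and number. The title of the series asks about polyunsaturated fat, septic Staphylococcus aureus infection and neutrophil function, and these arrays address marrow without infection. Array medians lay between 8.04 and 8.13 on the log2 scale, and Pearson's r between arrays, across genes that are not independent replicates, lay between 0.970 and 0.995. Any pair of arrays differed in at least 35554 of the 35556 probe sets, so no array was present more than once. The number of arrays limits the precision: the median standard error (SE) of a difference between diets was 0.085 on the log2 scale. The labels do not say that the arrays are separate animals, so the p-values measure the spread between these samples, which may be technical. Sample numbers run in blocks by diet, and no code in the sample descriptions is shared between diets. A batch or processing order that follows them cannot be told apart from diet.

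The interquartile range of the log2 values within an array, a sign of array quality, averaged 2.19 ± 0.051 (SD, n = 4) in LFD, 2.22 ± 0.036 in SFD and 2.26 ± 0.062 in PFD. By a two-sided exact permutation test, which cannot go below p = 0.0286 with 4 arrays against 4, its p was 0.371 for PFD against SFD, 0.143 for PFD against LFD and 0.314 for SFD against LFD. The first principal component held 37.6% of the variance and ran from LFD 3 at -21.25 to PFD 6 at 20.48. Its exact permutation p was 0.371, 0.171 and 0.429 in the same order. Along this component the arrays were ranked nearly as by interquartile range, which was lowest in LFD 3 (2.13) and highest in PFD 6 (2.34).

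**Figure D1:**
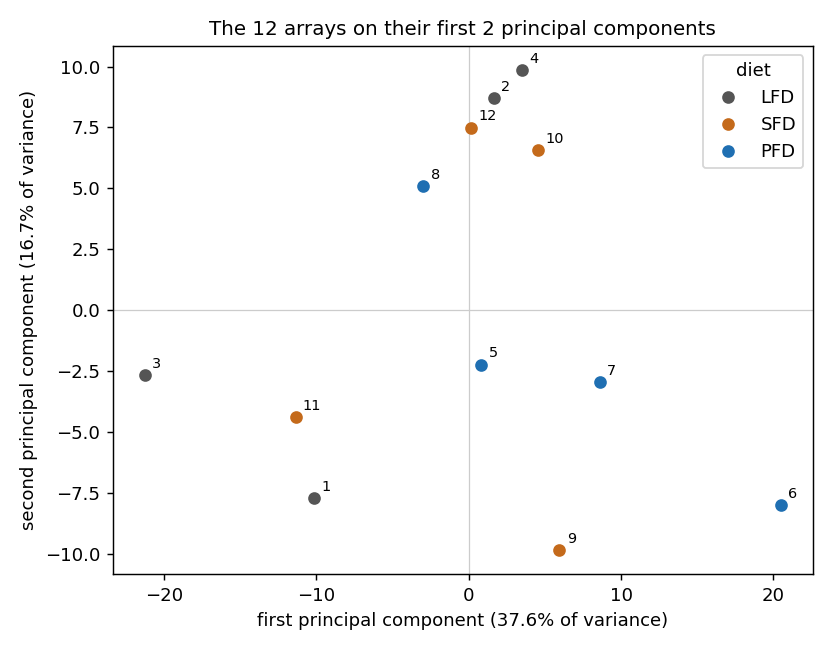
Each point is an array, coloured by diet and marked with its number, on the first principal component (37.6% of the variance, horizontal axis) and the second (16.7%, vertical axis), both in log2 units over the 15307 genes tested. LFD 3 and PFD 6 lie at the ends of the first component, and the diets overlap on both axes.

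The comparison of PFD with SFD asked which genes depend on the type of fat at a high fat intake. Of 15307 genes tested, 16 passed, 13 of them higher and 3 lower in PFD. An unadjusted p under 0.05 by limma was reached by 874 genes, where 765.4 are expected without any difference. Cd209f, a C-type lectin of the DC-SIGN family (probe set 10576835), differed by -1.33 ± 0.14 (log2, SE, n = 4 and 4, adjusted p = 0.000312). Its PFD mean, 7.12, lay under the level of 7.36 below which probe sets were left out as dim, close to the background signal, so the size of its fall is uncertain. Cd163, the macrophage scavenger receptor for haemoglobin bound to haptoglobin (probe set 10541644), was 35.8% lower (-0.64 ± 0.099, adjusted p = 0.0130). Col14a1, a collagen that associates with fibrils, was 36.4% lower (-0.65 ± 0.10, adjusted p = 0.0130). Among the higher genes, Gpnmb, a transmembrane glycoprotein of macrophages and osteoclasts, was 2.40-fold higher (1.26 ± 0.23, adjusted p = 0.0337). Its SD was 0.671 among the SFD arrays and 0.237 among the PFD arrays. Trem2, a lipid-sensing receptor of macrophages (probe set 10445781), was 1.60-fold higher (0.68 ± 0.092, adjusted p = 0.00398). In each of these genes, as in the other genes that passed, 4 of 4 PFD arrays lay beyond every SFD array.

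Fabp5, which carries fatty acids inside cells, was higher by 0.80 ± 0.12 (adjusted p = 0.0130), and its other probe set gave 0.82. Atp6v0d2, a subunit of the vacuolar proton pump, was higher by 0.91 ± 0.16 (adjusted p = 0.0303). Anxa4, an annexin that binds membrane phospholipids, was higher by 0.68 ± 0.089 (adjusted p = 0.00365), and the tetraspanin Tspan10 by 0.58 ± 0.073 (adjusted p = 0.00292). Clec7a, the fungal glucan receptor also called dectin-1, was higher by 0.58 ± 0.095 (adjusted p = 0.0201), and C3ar1, the receptor for complement C3a, by 0.52 ± 0.091 (adjusted p = 0.0321). Saa3, an acute-phase serum amyloid, was higher by 0.51 ± 0.096 (adjusted p = 0.0492). Atf3, a transcription factor induced by stress, was higher by 0.48 ± 0.086 (adjusted p = 0.0337), and Gstm1, a glutathione transferase, by 0.45 (adjusted p = 0.0303). S100a1, a calcium-binding protein, was higher by 0.53 ± 0.092 (adjusted p = 0.0303). Wfdc17, which encodes a small secreted protein with a whey acidic protein domain, was higher by 0.55 ± 0.098 (adjusted p = 0.0337). Its mean signal was 12.08 ± 0.145 (SD, n = 4) in PFD, 12.06 ± 0.189 in LFD and 11.53 ± 0.125 in SFD. The lower genes that came closest without passing were Egfl6 at -0.30, Arhgef12 at -0.28, Cd209g at -0.27, Cbr2 at -0.40 and Ncoa7 at -0.26 (adjusted p from 0.160 to 0.357).

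The fall in Cd209f and the rise in Trem2, Anxa4 and Tspan10 passed whichever array was left out (highest adjusted p 0.00342, 0.0217, 0.0229 and 0.0217). The 12 remaining genes each lost their call without some array. Their adjusted p reached 0.240 for Gpnmb, 0.0871 for Cd163 (without PFD 5 or PFD 7), Fabp5 and Col14a1. It reached 0.181 for Saa3, which did not pass without any single one of the 12 arrays. Of the 16 genes, 15 remained without LFD 1, LFD 2 or LFD 4, 14 without LFD 3, SFD 9 or PFD 8 and 12 without SFD 11. The whole count was 8 without SFD 10, 6 without SFD 12, 4 without PFD 5, 5 without PFD 6 and 6 without PFD 7. It was 7 with the interquartile range of the array as a covariate, 5 without both LFD 3 and PFD 6, 35 with the code in the sample description as a random block and 39 with array weights.

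**Figure D2:**
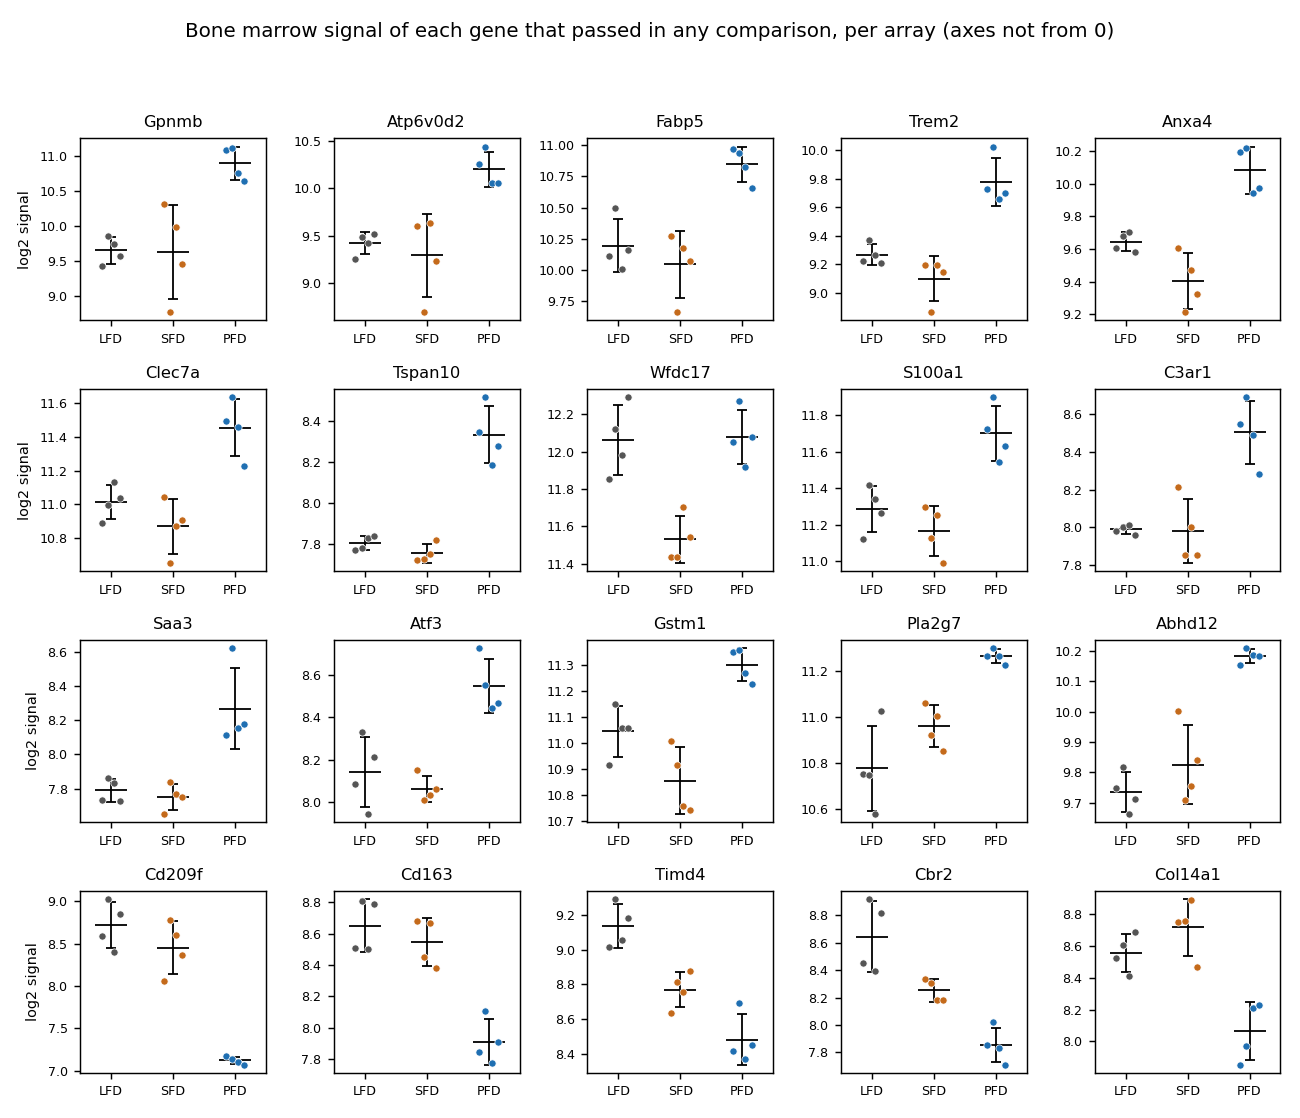
Each panel shows the log2 signal (vertical axis, not from 0) of a gene that passed in any comparison, with a point per array, grouped by diet along the horizontal axis, and the mean and SD of each diet as bars. For Cd209f the 4 PFD arrays average 7.12, below the LFD mean of 8.72 and the SFD mean of 8.45.

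Gene lists of neutrophils and of pathogen recognition had higher means in PFD than in SFD. By camera with a preset correlation, 25 of the 51 lists passed, 20 higher and 5 lower. The higher lists were not confined to neutrophils and pathogen recognition. They also included inflammasome and pyroptosis (0.12), circadian clock genes (0.11), NK cell markers (0.086), glycolysis and hypoxia response (0.083) and pro-B and pre-B cell markers (0.079). With an estimated correlation 0 passed, with 4 lists at an unadjusted p under 0.05. By fry 0 passed. By an exact permutation test of list means 0 had an unadjusted p under 0.05. After adjustment 0 passed by that test, a count that could hardly be higher. Fc and complement receptors had a mean difference of 0.18 over 13 members, 11 of them positive (adjusted p = 1.36e-06; adjusted p = 0.538 with an estimated correlation). Of these, C3ar1 was higher over all genes and 4 members were higher adjusted over the list alone, among them Fcgr4 (0.30 ± 0.082) and Fcer1g (0.26 ± 0.076). Primary granule proteins of neutrophils, which kill and digest microbes, differed by 0.18, with 11 of 11 members positive (adjusted p = 7.58e-06; adjusted p = 0.550 with an estimated correlation). Over all genes 0 of them passed by limma, and 1 adjusted over the list alone. Their examples include Cd63 (0.35 ± 0.098), Ctsg (0.23 ± 0.094) and Elane (0.23 ± 0.097), none of which passed over all genes. Toll-like receptors and other bacterial recognition genes differed by 0.14 over 19 members (adjusted p = 1.34e-05; adjusted p = 0.538 with an estimated correlation). Clec7a was higher over all genes and 2 members were higher adjusted over the list alone. Mature neutrophil markers differed by 0.15 over 17 members (adjusted p = 1.63e-05; adjusted p = 0.538 with an estimated correlation). Of these, 0 passed over all genes by limma and 2 adjusted over the list alone, such as Ccl6 at 0.32 ± 0.084.

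Monocyte and macrophage markers moved both ways. Their mean was higher in PFD by 0.10 over 24 members (adjusted p = 0.000131; adjusted p = 0.550 with an estimated correlation). Cd163 was lower over all genes, and 3 members were higher and 2 lower adjusted over the list alone. Cd68, a lysosomal glycoprotein of macrophages, differed by 0.40 ± 0.079 and C1qb, a chain of complement C1q, by 0.30 ± 0.084, and neither passed over all genes. Secondary and tertiary granule proteins differed by 0.10 over 21 members and genes of the NADPH oxidase and of neutrophil killing by 0.093 over 11 (adjusted p = 0.000311 and 0.00456; adjusted p = 0.550 for both with an estimated correlation). In both lists 0 members passed by limma, over all genes or adjusted over the list alone. Cartilage markers were lower by a mean difference of -0.12, with 8 of 9 members negative and 0 passing by limma (adjusted p = 0.000311; adjusted p = 0.538 with an estimated correlation). Markers of megakaryocytes and platelets (-0.19), stroma and osteoblasts (-0.14) and erythroid cells (-0.080) and the TGF-beta, matrix and fibrosis list (-0.11) were lower in PFD too (adjusted p = 0.000396, 0.000934, 0.000454 and 0.0150; adjusted p from 0.550 to 0.582 with an estimated correlation). In these 4 lists 0 members passed by limma, over all genes or adjusted over the list alone. The megakaryocyte call was lost without SFD 9 or PFD 8 (mean differences of -0.023 and -0.086, adjusted p up to 0.522) and the stromal call without SFD 9 or PFD 5 (-0.098 and -0.075, adjusted p up to 0.0606). The erythroid call was lost without PFD 5 (-0.041, adjusted p = 0.0589), and that of the TGF-beta list without SFD 9, SFD 11, PFD 5 or PFD 8 (nearest to 0 without PFD 5, at -0.057; adjusted p up to 0.115). For the Fc receptor, granule, Toll-like receptor and mature neutrophil lists the mean of 3 of 4 PFD arrays lay above every SFD array, and for the monocyte and macrophage list that of 2 of 4. The interquartile range of the arrays was higher in PFD than in SFD by 0.037 (exact permutation p = 0.371). Across the 25 lists the adjusted p with an estimated correlation ran from 0.538 to 0.625. The calls of 10 lists held whichever array was left out, among them the Fc receptor, Toll-like receptor, mature neutrophil, monocyte and macrophage, NADPH oxidase and cartilage lists and both granule lists. Those of 15 lists were lost without at least 1 of the SFD or PFD arrays, with adjusted p up to 0.717.

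**Figure D3:**
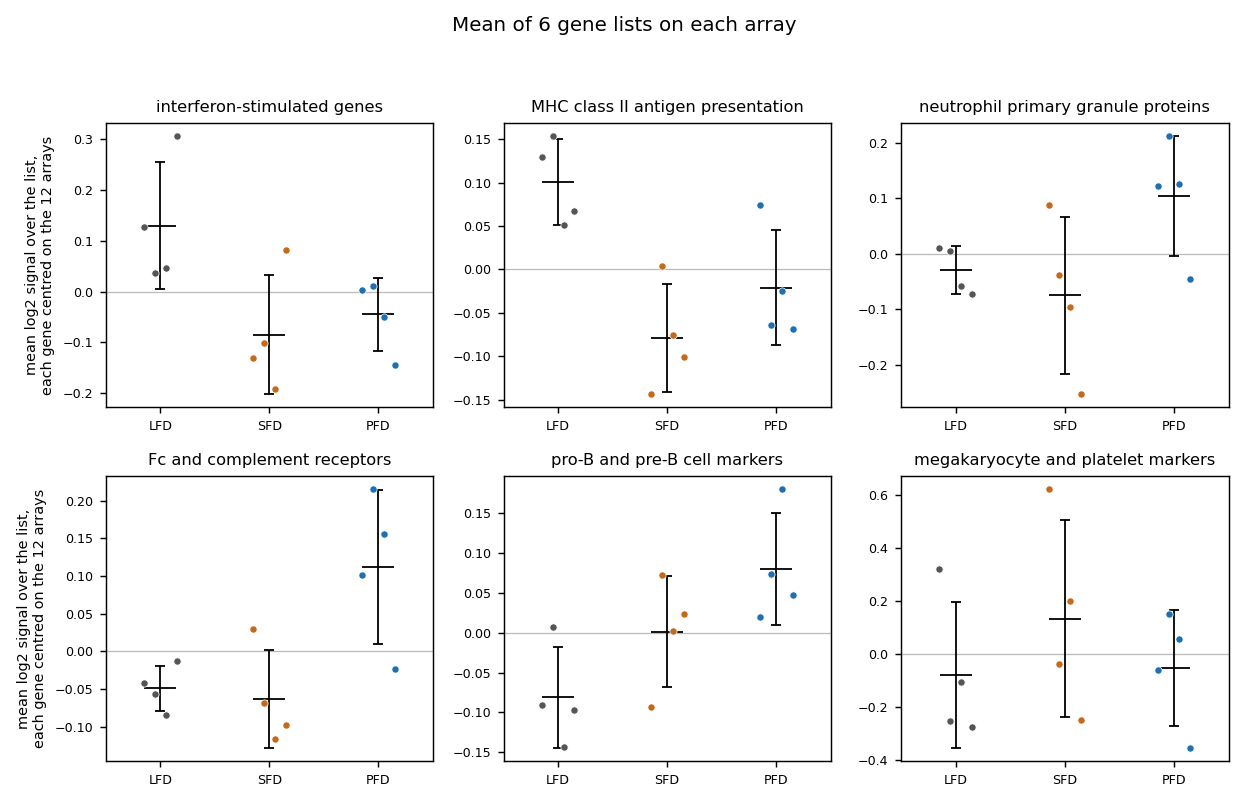
Each panel shows the mean log2 signal over the members of a gene list on each array (vertical axis, each gene centred on the 12 arrays), with a point per array, grouped by diet along the horizontal axis, and the mean and SD of each diet as bars. Interferon-stimulated genes and MHC class II genes average highest in LFD, and Fc and complement receptors in PFD, where 1 array lies below the highest SFD array.

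The comparison of PFD with LFD asked what a polyunsaturated high fat diet changes relative to a low fat diet, and 7 of 15307 genes passed, 4 lower and 3 higher. An unadjusted p under 0.05 by limma was reached by 1933 genes, where 765.4 are expected without any difference. With single arrays left out this count ran from 833 (without PFD 6) to 2827 (without PFD 8). Cd209f differed by -1.60 ± 0.14 (log2, SE, n = 4 and 4, adjusted p = 2.08e-05), a size that is uncertain for the same reason, and Cd163 was 40.2% lower (-0.74 ± 0.099, adjusted p = 0.00342). Timd4, a phosphatidylserine receptor of resident macrophages (probe set 10375472), was 36.4% lower (-0.65 ± 0.086, adjusted p = 0.00342), and Cbr2, a carbonyl reductase (probe set 10393936), 42.3% lower (-0.79 ± 0.11, adjusted p = 0.00342). Tspan10 was 1.44-fold higher (0.53 ± 0.073, adjusted p = 0.0040). Pla2g7, the lipoprotein-associated phospholipase that degrades platelet-activating factor, was higher by 0.49 ± 0.084 (adjusted p = 0.0481), and Abhd12, a lysophosphatidylserine lipase, by 0.45 ± 0.072 (adjusted p = 0.0229). All 7 had 4 of 4 PFD arrays beyond every LFD array.

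Several genes that passed against SFD lay near the threshold against LFD without passing it. Gpnmb differed by 1.24 ± 0.23 (adjusted p = 0.0605), Trem2 by 0.51 ± 0.092 and C3ar1 by 0.51 ± 0.091 (adjusted p = 0.0569 for both). Fabp5 differed by 0.65 ± 0.12 (adjusted p = 0.0788) and Col14a1 by -0.49 ± 0.10 (adjusted p = 0.0923). Epb41l3 at 0.44, Cd209g at -0.37, Vstm4 at -0.35 and H2-Eb1, a beta chain of MHC class II, at -0.46 also did not pass (adjusted p from 0.0788 to 0.0821). The 4 lower genes and Tspan10 passed whichever array was left out. Pla2g7 lost its call without any one of LFD 1, LFD 2, LFD 3, SFD 11, SFD 12 or the PFD arrays (adjusted p up to 0.188). Abhd12 lost it without LFD 1, LFD 3, LFD 4, PFD 5, PFD 6 or PFD 7 (adjusted p up to 0.108). The count rose to 13 without SFD 10 and 16 without PFD 8, and to 45 with the description code as a random block. It was 13 with array weights or with only PFD and LFD fitted, 14 with array medians subtracted and 16 with an intensity trend.

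Interferon-stimulated genes, which antiviral cytokines induce, were lower in PFD than in LFD by a mean difference of -0.17 over 28 members, 25 of them negative (adjusted p = 7.53e-08; adjusted p = 0.561 with an estimated correlation). By limma 0 members passed over all genes and 4 were lower adjusted over the list alone, such as Ifit1 (-0.50 ± 0.13) and Irf7 (-0.34 ± 0.10). Without LFD 4 the mean difference of the list was -0.12. The list of MHC class II antigen presentation differed by -0.12 over 9 members (adjusted p = 0.00248; adjusted p = 0.482 with an estimated correlation). By limma 0 of them passed over all genes and 4 were lower adjusted over the list alone, H2-Eb1, Cd74 (-0.30 ± 0.066), H2-Ab1 and H2-Aa. Cartilage markers differed by -0.16, with 9 of 9 members negative (adjusted p = 0.000202; adjusted p = 0.482 with an estimated correlation). By limma 0 passed over all genes and 3 were lower adjusted over the list alone, such as Sox9 at -0.27 ± 0.085. Markers of pro-B and pre-B cells, the precursors of B cells, had a higher mean by 0.16 over 21 members (adjusted p = 0.00022; adjusted p = 0.501 with an estimated correlation). By limma 0 of them passed over all genes or adjusted over the list alone, and examples are Rag1 (0.33 ± 0.12) and Il7r (0.33 ± 0.11). Fc and complement receptors differed by 0.16, with 6 members higher and 1 lower adjusted over the list alone (adjusted p = 0.00477; adjusted p = 0.738 with an estimated correlation). In all, 17 lists passed by camera with the preset correlation, 13 higher and 4 lower. The higher lists included Toll-like receptors and bacterial recognition (0.13) and the primary (0.13) and secondary and tertiary (0.10) granule proteins of neutrophils. Both granule calls were lost without LFD 4 or PFD 5, the primary also without PFD 7 and the secondary also without LFD 2 (adjusted p up to 0.153). Mature neutrophil markers, at 0.10, did not pass. None of the 17 lists passed with an estimated correlation (0, with 5 at an unadjusted p under 0.05), and 0 passed by fry. By the exact test 3 lists had an unadjusted p of 0.0286, the smallest it can give. After adjustment 0 passed by that test, a count that could hardly be higher. All 4 of 4 PFD arrays lay beyond every LFD array for the interferon, cartilage and pro-B lists, and 3 of 4 for MHC class II and the Fc receptors. The interquartile range of the arrays was higher in PFD by 0.071 (exact permutation p = 0.143).

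The comparison of SFD with LFD asked the same of a saturated high fat diet. By limma 0 of 15307 genes passed, and 506 had an unadjusted p under 0.05 where 765.4 are expected without any difference. The genes named for their small unadjusted p include Ace, angiotensin-converting enzyme, at 0.81 ± 0.14 (adjusted p = 0.294) and Cd300e, a receptor of monocytes, at 0.59 ± 0.15 (adjusted p = 0.977). Oasl2, an interferon-induced gene, differed by -0.56 ± 0.11 (adjusted p = 0.385) and Wfdc17 by -0.53 ± 0.098 (adjusted p = 0.356). Acot1, an acyl-CoA thioesterase, differed by 0.42, Serpinb2 by 0.48, Adgre4 by 0.33, Egfl6 by 0.30, S1pr5 by 0.29 and Eif5a2 by 0.25 (adjusted p from 0.844 to 0.977). Fcgr1, the high-affinity Fc receptor, differed by -0.40 ± 0.079 (adjusted p = 0.385) and Timd4 by -0.37 ± 0.086 (adjusted p = 0.844). With the interquartile range of the array as a covariate 2 genes passed.

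Interferon-stimulated genes and MHC class II genes had the smallest adjusted p of the lists in this comparison. All 28 interferon-stimulated genes were lower in SFD, with a mean difference of -0.21 and 3 of 4 SFD arrays below every LFD array (adjusted p = 1.83e-19; adjusted p = 0.247 with an estimated correlation). By limma 0 of them passed over all genes and 7 were lower adjusted over the list alone, such as Ifit1 (-0.51 ± 0.13) and Ifit3 (-0.44 ± 0.11). The MHC class II list differed by -0.18, with 4 of 4 SFD arrays below every LFD array (adjusted p = 3.46e-09; adjusted p = 0.0692 with an estimated correlation; adjusted p = 0.0364 by fry). Of its 9 members, 4 were lower adjusted over the list alone, H2-Eb1 (-0.42 ± 0.088), H2-Aa (-0.36 ± 0.076), H2-Ab1 (-0.32 ± 0.066) and the invariant chain Cd74 (-0.28 ± 0.066), and 0 over all genes by limma. Stromal and osteoblast markers had a higher mean in SFD by 0.20 over 21 members (adjusted p = 4.5e-05; adjusted p = 0.530 with an estimated correlation). Its members had 0 calls by limma, over all genes or adjusted over the list alone, and examples are Igfbp5 (0.60 ± 0.18) and Col1a1 (0.55 ± 0.23). The TGF-beta, matrix and fibrosis list differed by 0.18, with 2 members higher adjusted over the list alone (adjusted p = 7.81e-05; adjusted p = 0.530 with an estimated correlation). Megakaryocyte and platelet markers differed by 0.21 over 17 members, with 1 of 4 SFD arrays above every LFD array and 0 members passing by limma, over all genes or adjusted over the list alone (adjusted p = 0.000291; adjusted p = 0.960 with an estimated correlation). This call was lost without LFD 2, LFD 4 or SFD 9 (mean differences down to 0.050, adjusted p up to 0.464). Monocyte and macrophage markers differed by -0.093 over 24 members and by -0.060 without SFD 12 (adjusted p = 3.53e-06; adjusted p = 0.530 with an estimated correlation). Timd4 was lower adjusted over the list alone. Markers of NK cells (-0.11) and T cells (-0.082) were lower in SFD too (adjusted p = 0.000228 and 0.00212; adjusted p = 0.530 and 0.607 with an estimated correlation). Both calls were lost without LFD 4, the array with the highest mean of the interferon list (-0.043 and -0.038, adjusted p = 0.166 and 0.186). Mature neutrophil markers differed by -0.047 (adjusted p = 0.0414; adjusted p = 0.930 with an estimated correlation), a call lost without any one of LFD 1, LFD 2, LFD 4, SFD 10, SFD 11 or SFD 12 (adjusted p up to 0.408; mean differences from -0.086 to -0.015 over the 12 arrays left out in turn). In all, 16 lists passed with the preset correlation, 9 higher and 7 lower. With an estimated correlation 0 passed (4 at an unadjusted p under 0.05), and by fry 1. By the exact test 1 list had an unadjusted p under 0.05. After adjustment 0 passed by that test, a count that could hardly be higher. The interquartile range of the arrays was higher in SFD by 0.034 (exact permutation p = 0.314).

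The mean of both high fat diets was set against LFD to ask what a high fat intake changes whatever the fat. An unadjusted p under 0.05 by limma was reached by 1245 genes, where 765.4 are expected without any difference. Here 3 genes passed, all lower: Cd209f (-0.93 ± 0.12, adjusted p = 0.00648, 6 of 8 arrays below every LFD array), Timd4 (-0.51 ± 0.075, adjusted p = 0.0217, 8 of 8) and Cbr2 (-0.59 ± 0.092, adjusted p = 0.0298, 8 of 8). The mean for Cd209f comes mostly from PFD (-1.60), with SFD at -0.265 against LFD (adjusted p = 0.977, 2 of 4 arrays below every LFD array), and its size is uncertain because the PFD mean lay under the dim level. In SFD alone Timd4 differed by -0.37 and Cbr2 by -0.39, and neither passed. Ace differed by 0.66 ± 0.12 (adjusted p = 0.120, 8 of 8), Acot1 by 0.41 (adjusted p = 0.280, 8 of 8), H2-Eb1 by -0.44 ± 0.076 (adjusted p = 0.0883, 8 of 8) and Oasl2 by -0.50 ± 0.098 (adjusted p = 0.182, 7 of 8), and none of these passed. Nor did Pla2g7 at 0.33, Serpinb2 at 0.44, R3hcc1l at 0.31, Abhd12 at 0.27, Rab3gap2 at 0.26, Eps8 at 0.25, H2-Aa at -0.33, Cd74 at -0.29 and H2-Ab1 at -0.29 (adjusted p from 0.182 to 0.534). By camera with the preset correlation 14 lists passed, 8 higher and 6 lower. With an estimated correlation 0 passed, with 5 at an unadjusted p under 0.05, and by fry 1. Interferon-stimulated genes differed by -0.19 (7 of 8 arrays below every LFD array, 8 members lower adjusted over the list alone; adjusted p = 0.329 with an estimated correlation). MHC class II genes differed by -0.15 (7 of 8 arrays, 4 members; adjusted p = 0.255 with an estimated correlation, 0.0287 by fry). The call of Cd209f was lost without LFD 4 (adjusted p = 0.0552). The call of Timd4 was lost without LFD 2, LFD 4, PFD 5, PFD 7 or PFD 8 (adjusted p up to 0.140), and the call of Cbr2 without these or any of SFD 10, SFD 11 and SFD 12 (adjusted p up to 0.149). The count was 0 without LFD 4 by limma, and 1 without each of LFD 2, PFD 5, PFD 7 and PFD 8.

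The genes that passed in PFD against SFD and against LFD overlapped in Tspan10 among the higher genes and in Cd163 and Cd209f among the lower genes. Independent lists of these sizes would share 0.00255 higher and 0.000784 lower genes. Both comparisons share the PFD arrays. In 100 simulated sets of 3 unchanged groups at most 0 genes were shared, and since 0 of these sets had calls in both comparisons, this says nothing about sharing once genes are called. In 100 further sets the differences of the 16 and the 7 genes were put on separate random genes, in SFD alone and in LFD alone. These sets called a median of 13 and 5 genes and shared a mean of 0.01 and at most 1. With the PFD arrays halved between the comparisons, in 6 ways, 1 to 2 genes were shared in all.

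Across genes, which are not independent replicates, the differences of PFD and of SFD from the shared LFD arrays had a covariance of 0.00713 (Pearson's r = 0.605). Simulated sets of 3 unchanged groups, with a shared control in the same way, gave a mean covariance of 0.00510 (95% from -0.000831 to 0.0139; mean r = 0.483), and 235 of 1000 simulations reached the observed value. With the LFD arrays split between both differences the mean covariance over 6 splits was 0.00155 (from -0.00541 to 0.00431; mean r = 0.122). With single arrays left out the covariance ran from 0.00509 (without LFD 3) to 0.0121 (without LFD 4), and it was 0.00373 with the interquartile range of the array as a covariate. With all 12 arrays, a shared shift of both high fat diets across genes was not distinguished from what the shared controls alone can give.

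Of 20 genes chosen in advance for their roles in lipid metabolism, neutrophils and other marrow cells, 16 could be tested and 0 passed in any comparison by limma. In PFD against SFD, Scd1, the stearoyl-CoA desaturase, differed by -0.19 ± 0.076, Fasn, fatty acid synthase, by -0.068 and Fads2, a desaturase of polyunsaturated fatty acids, by -0.082. Against LFD, Scd1 differed by -0.26 in PFD and -0.068 in SFD. Cpt1a, which admits fatty acids to mitochondrial oxidation, differed by 0.24 ± 0.073 in PFD and 0.23 ± 0.073 in SFD, with 4 of 4 arrays of either diet above every LFD array (adjusted p = 0.320 and 0.977). The lipoprotein lipase inhibitor Angptl4 differed by 0.16 in PFD against SFD. The neutrophil genes Mpo, Elane, Ltf, Camp, Ngp, S100a8, Cxcr2 and Csf3r differed by 0.10, 0.23, 0.0081, 0.10, 0.088, 0.048, 0.13 and 0.19 in PFD against SFD (adjusted p from 0.836 to 0.996). In the same comparison the B cell gene Cd79a differed by 0.045, the adipocyte gene Adipoq by 0.12 and the collagen gene Col1a1 by -0.43 ± 0.23.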

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

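The tests of macrophages of all kinds, of a lipid-laden macrophage state, of B cells and of correlated list members were chosen only after the results they address had been seen, as were the interquartile range as a covariate, the leaving out of LFD 3 and PFD 6, odd or even sample number as a covariate and the use of array medians in other splits.

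In 3 of 168 groups of 4 arrays, a single array stood far from the other arrays of its diet, where chance gives about 1 in 20 groups, or 8.4. Saa3 was at 8.621 in PFD 6 against 8.115 to 8.177 in the other PFD arrays. Trem2 was at 8.866 in SFD 10 against 9.143 to 9.195 in the other SFD arrays. The array median of SFD 11 was 8.123 against 8.053 to 8.059 in the other SFD arrays.

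Under PFD, Cd209f, Cd163, Timd4 and Cbr2 fell against LFD (the smallest difference was -0.65) while 13 genes, among them Trem2, Gpnmb and Fabp5, were higher than in SFD. A lower number of macrophages of all kinds is argued against: the list of monocyte and macrophage markers, which holds Cd163 and Timd4, differed by 0.0101 between PFD and LFD (95% from -0.0986 to 0.119), where the smallest fall was -0.65 (-0.835 to -0.472), and 16 core macrophage genes differed by 0.0382 (-0.0984 to 0.175). A higher number of macrophages as the whole of the rise is argued against only weakly, and for 12 of the 13 genes. The list of monocyte and macrophage markers differed by 0.103 between PFD and SFD (-0.00537 to 0.212). The core list, written after the calls and without any called gene, differed by 0.162 (0.0254 to 0.299). Its exact permutation p was 0.0286, with an adjusted p of 0.0857 over 6 tests. The lowest lower bound of the 12 was 0.3005, that of Atf3, barely above the core list's upper bound of 0.2986. The 12 genes were also picked for their rise, and the list of monocyte and macrophage markers holds Cd163, which fell (-0.64). For Gstm1, with the smallest rise, 0.45 (0.283 to 0.607), a higher number of macrophages could not be excluded, since the interval of the core list overlaps. As part of the rise it stays open for all 13. Array quality, as far as the interquartile range measures it, is argued against as the whole cause. The median ratio between the differences with and without it as a covariate was 0.958 (0.808 to 1.27 over 26 calls). Only 7 genes, 6 of them among the 16, passed against SFD in that fit, and why the other calls ended was not tested. Nor were other sides of array quality. A shift of macrophages towards a lipid-laden state stays open as a hypothesis: 34 further genes of that state differed by 0.186 between PFD and SFD (0.0586 to 0.312; exact permutation p = 0.0571, adjusted p = 0.114), and by 0.193 between PFD and LFD (exact permutation p = 0.0286, adjusted p = 0.0857).

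Lists of interferon-stimulated and MHC class II genes were lower under both high fat diets, which are set against the same LFD arrays. A single LFD array as the cause is argued against, since at least 0.696 of either shift was left whichever LFD array was left out, the lowest being that of the interferon list without LFD 4. Array quality, as far as the interquartile range measures it, is argued against too, since at least 0.984 was left with it as a covariate. Other sides of array quality were not tested. Fewer B cells, which carry MHC class II, could not be excluded as the cause of the MHC class II shift of -0.15. Mature B cell markers differed by 0.0570 (95% from -0.138 to 0.252), but by -0.0446 (-0.173 to 0.0834) without LFD 3, where the MHC class II shift was -0.167. NK and T cell markers differed by -0.069 and -0.058, with 1 of 8 arrays below every LFD array for either list, and their SFD differences went from -0.112 and -0.082 to -0.043 and -0.038 without LFD 4. Fewer of these cells were not tested as a cause. An effect of fat intake on interferon signalling and antigen presentation may remain, as a hypothesis, and neither list passed with an estimated correlation between members.

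Of the 25 lists that differed between PFD and SFD with a preset correlation, 0 kept their call with an estimated correlation, a share of 0, which is what correlated members would give. A share of 0.64 kept it with the interquartile range as a covariate and 0.72 without LFD 3 and PFD 6, which lie between the shares set in advance for and against array quality and these arrays as the cause. Both may contribute and could not be excluded, and they are not separate accounts. The interquartile range and the first component ranked the arrays nearly alike, with LFD 3 lowest and PFD 6 highest on both. A real difference in the share of neutrophils or other marrow cells was not tested.

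Other splits of the arrays into groups of 4 show how often another division of the arrays gave as many calls. They cannot set diet apart from a batch or processing order that follows the diets, since sample numbers run in blocks by diet. For genes a chance division is argued against for PFD against SFD, but not excluded. The real split gave 16 genes and another at most 1, and 1 of 35 splits reached the real count. That is the smallest share 35 splits can give, and it was not adjusted for the number of comparisons. The same holds for PFD against LFD (7 and at most 0, and 1 of 35). For both high fat diets against LFD 2 of 100 drawn splits, the real one included, reached the real count of 3, a share under the limit set in advance. Here too chance is not excluded, since another draw gave 1370 and the real count was 0 without LFD 4. For SFD against LFD the count says nothing on chance, since its real value is 0, which all 35 of 35 splits reach by construction, and another split gave 563. For lists chance cannot be excluded in any of the 4 comparisons: 2 of 35 splits reached the 25 lists of PFD against SFD (highest other 26), 11 of 35 the 17 of PFD against LFD (26), 15 of 35 the 16 of SFD against LFD (29) and 48 of 100 drawn splits the 14 of both high fat diets against LFD (30).

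The split with 563 genes set LFD 1, LFD 3, SFD 9 and SFD 11 against LFD 2, LFD 4, SFD 10 and SFD 12, and the next highest count was 2. A split that calls so many genes where the diets called 0 points to a structure of the samples other than diet, and what it is was not settled. In LFD and SFD this split follows odd and even sample numbers. The draw with 1370 genes took LFD 1, LFD 3, SFD 11 and PFD 5 as LFD. These are odd numbers, but SFD 9 and PFD 7 stayed on the other side, and they are also the 4 arrays with the highest medians (8.087 to 8.132, the others at most 8.066). With array medians subtracted both splits still called many genes (1085 and 3090), so a shift of whole arrays does not account for them. With the median as a covariate 127 and 0 were left, where a fall of the second count is expected because the median sets these 4 arrays apart. LFD 1, LFD 3 and SFD 11, which both splits put together, also had the lowest interquartile ranges (2.164, 2.130 and 2.179). SFD 9 (2.261) and PFD 5 (2.235), put with them in one split each, did not. Whether the interquartile range accounts for these splits was not tested. Within PFD the second component of the values centred on each diet did not separate odd from even (0.0531 and -0.0827 against -0.359 and 0.389). On the second principal component 6 of 6 odd arrays lay below 0 and 5 of 6 even arrays above it, PFD 6 being the exception. With odd or even number as a covariate 17 genes passed for PFD against SFD, including the 16, and 11 for PFD against LFD, including the 7, with 0 for SFD against LFD and 4 for both high fat diets.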

How the results depend on the processing

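The interquartile range as a covariate, the leaving out of LFD 3 and PFD 6, the exact test of list means and odd or even sample number as a covariate were chosen only after the data had been seen.

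No gene or list call changed direction under any alternative run, while some differences near 0 that had not passed did. Of 540 values of the 26 gene calls under settings chosen in advance, 433 kept direction and call and 107 kept direction only, and of 78 under those chosen later, 53 and 25. For the 58 list calls these numbers were 1024 and 250 of 1274, and 135 and 39 of 174. Of 13436 values under settings chosen in advance of 647 gene differences that had not passed, 81 passed and 81 moved by more than their spread, as did 7 and 169 of 1936 chosen later.

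The count of genes for PFD against SFD (16) ran from 4 to 24 with single arrays left out, and was 39 with array weights, 35 with the description code as a random block, 7 with the interquartile range as a covariate, 5 without LFD 3 and PFD 6 and 28 at an adjusted p under 0.10. For PFD against LFD (7) it ran from 5 to 16, and was 14 with array medians subtracted, 16 with an intensity trend and robust estimation, 13 with array weights, 45 with the block, 11 with odd or even number as a covariate, 25 at an adjusted p under 0.10 and 13 with only these 2 diets fitted. For SFD against LFD (0) it was 2 with the interquartile range as a covariate. For both high fat diets against LFD (3) it ran from 0 to 4, and was 1 with array medians subtracted, 5 with the intensity trend, 8 with the block and 6 with the interquartile range. The estimated correlation, fry and the exact test left 0, 0 and 0 lists for PFD against SFD, 0, 0 and 0 for PFD against LFD, and 0, 1 and 0 for SFD against LFD. With single arrays left out the lists ran from 11 to 22 for PFD against LFD, with 8 at a filter of 50%, and from 10 to 19 for SFD against LFD. With single arrays left out the covariance of the differences from LFD ran from 0.00509 (without LFD 3) to 0.0121 (without LFD 4), and it was 0.00373 with the interquartile range as a covariate and 0.00427 without LFD 3 and PFD 6.

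A looser threshold raises a count by construction, the block is taken up below, and for the other settings the cause was not tested. A pseudocount did not apply to log2 values, lists were not run with the block, and the high fat comparison and the covariance need all 3 diets. The meaning of the description codes is not given in the sources used here, and the correlation within them was -0.12. A negative correlation lowers the SE between diets that share no code, so the higher counts with the block are not read as more changed genes. Genes near the filter level of 7.36, such as Cd209f in PFD, have little signal over background, and no array records its own background here. The LFD and SFD means of Tspan10, Saa3 and C3ar1 lay above that level but below every array median.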

Other observations

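The gene lists below were fixed in advance, and no test in this part was chosen after its result was seen except the naming of the Cd209 genes.

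Lists of plasma cells, of mast cells, basophils and eosinophils and of PPAR targets had higher means under both high fat diets. Both diets are set against the same LFD arrays, so a likeness between their differences can come from those arrays alone. Plasma cell markers differed by 0.19 in PFD and 0.12 in SFD against LFD, with examples Jchain (0.48 ± 0.23 and 0.50 ± 0.23), the joining chain of secreted antibodies, and Irf4 (0.29 and 0.17), a transcription factor of plasma cells (adjusted p = 0.00462 and 0.0204; adjusted p = 0.501 and 0.607 with an estimated correlation). In PFD 3 members were higher adjusted over the list alone, and the SFD call was lost without LFD 2, LFD 3, LFD 4, SFD 10 or SFD 11 (adjusted p up to 0.132; 0.082 without LFD 3). Markers of mast cells, basophils and eosinophils differed by 0.16 and 0.097, with Prg3, an eosinophil granule protein, at 0.31 and 0.20 (adjusted p = 0.00575 and 0.0127; adjusted p = 0.850 and 0.930 with an estimated correlation), and both calls were lost without LFD 4 (mean differences of 0.12 in PFD and 0.054 in SFD, adjusted p = 0.133 in PFD), that of SFD also without SFD 9, at 0.052, or SFD 11, at 0.094 (adjusted p up to 0.408). Targets of PPAR and of fatty acid oxidation differed by 0.11 and 0.072, with Acot1 at 0.41 and 0.42 and Cpt1a at 0.24 and 0.23 (adjusted p = 0.0163 and 0.00886; adjusted p = 0.850 and 0.960 with an estimated correlation), and both calls were lost without LFD 1 or LFD 3 and that of SFD without SFD 10 (mean differences down to 0.073 in PFD and 0.037 in SFD, both without LFD 3; adjusted p up to 0.0866 in PFD and 0.241 in SFD). Skeletal muscle markers, which marrow itself does not express, differed by -0.14 and -0.087, with Ckm at -0.18 and -0.14 (adjusted p = 0.00151 and 0.00344; adjusted p = 0.482 and 0.530 with an estimated correlation), and the SFD call was lost without LFD 2, LFD 4 or SFD 10 (mean differences of -0.051, -0.057 and -0.060, adjusted p up to 0.126). Of 4 arrays, 3 of PFD and 1 of SFD lay beyond every LFD array for plasma cells, 3 and 3 for mast cells, basophils and eosinophils, 2 and 1 for the PPAR list and 3 and 2 for muscle.

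Lipid lists gave small differences. The eicosanoid and lipid mediator list differed by 0.10 between PFD and LFD, with Pla2g7 passing, and its call was lost without LFD 4 or PFD 6, at 0.098 and 0.066 (adjusted p = 0.0237; 0.0946 without the worse of these; adjusted p = 0.850 with an estimated correlation). Targets of LXR and genes of cholesterol efflux differed by 0.094 between PFD and SFD, with Abcg1, a cholesterol exporter, at 0.26 ± 0.073, and the call was lost without SFD 12, at 0.075, and kept without PFD 6, at 0.061 (adjusted p = 0.0155; 0.0527 without SFD 12; adjusted p = 0.550 with an estimated correlation). The list of sterol biosynthesis differed by 0.00 between PFD and SFD and 0.057 between PFD and LFD, and oxidative phosphorylation by 0.048 between PFD and LFD, and neither passed. Fatty acid synthesis and desaturation did not pass between PFD and LFD, and its mean of -0.017 and its median of 0.021 differ in sign.

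The fall of Cd209f was not shared by all members of its family. Between PFD and LFD the difference was -0.37 ± 0.070 for Cd209g, -0.058 for Cd209a, -0.044 for Cd209c and 0.099 for Cd209d, none of which passed, and these genes were chosen after their values were seen.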
